A study of Caenorhabditis elegans and Caenorhabditis briggsae and Caenorhabditis japonica with 30 samples.

How the data were processed

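Whole animals of 5 Caenorhabditis species were analysed, XX and XO separately, in 3 replicate libraries per species and sex. Per the labels' protocols, poly(A) RNA was sequenced as single-end reads. Groups and replicate numbers were taken from the sample titles. The labels describe each replicate as its own pool of picked animals. The base-caller version differed between replicate 1 and replicates 2 and 3 in every species but C. briggsae, and C. brenneri XX replicate 1 had a version of its own.

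The submitters' processing notes name TopHat 1.2.0, Bowtie 0.12.7 and Cufflinks 1.0.3, without saying which step each was used for. The genome builds, the annotations and the use of strand are not given in the sources used here. Each species has 2 deposited tables. Per the file headers, the first gives the authors' FPKM (fragments per kilobase, scaled to the library) of each gene in the 6 libraries, and the second gives RPKM of contigs assembled from the reads. Both tables carry the authors' mean per sex, the authors' deposited p-values and a mark for differential genes or contigs. The test behind these p-values is not given in the sources used here, and they were used only for the counts quoted from that table. Contig sequences were present for lengths from 50 to 199 nucleotides. All columns of values per sample could be mapped to samples.

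For the contigs given with a sequence, RPKM multiplied by length was a whole multiple of its smallest value above 0, taken as 1 read, in 100% of values within a tolerance of 0.001. This gave the mapped reads behind each library, 5980705 to 8870218 in C. elegans, 10112573 to 14857757 in C. briggsae, 6872437 to 20368766 in C. remanei, 8769729 to 24009713 in C. brenneri and 7834680 to 19082563 in C. japonica. More reads narrow the error of low genes, and no interval per gene was computed from them. FPKM values are not counts and no count model was used. The 10 highest genes held between 8.38% and 59.3% of a library's summed FPKM, most in C. japonica (42.3% to 59.3%) and in C. remanei XO (34.0% to 53.3%). No libraries were duplicates: the chi-square per degree of freedom between 30 pairs of replicates lay between 1.66 and 41.9.

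Each species was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust, statmod 1.5.0) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested. No covariate was used. Contigs were tested in the same way. With 3 libraries per sex the p-values rest on the spread between these pools. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists with at least 5 genes tested. Camera with an estimated correlation and fry were alternatives. With the estimated correlation no list was called, with adjusted p from 0.433 to 0.84.

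The test was tried on simulated data with known changes in a small share of genes. The noise was independent between genes and drawn from the spread of the XO libraries. Of genes changed 2-fold, 73.5% were recovered in C. elegans, 24.0% in C. briggsae, 79.8% in C. remanei, 22.6% in C. brenneri and 69.7% in C. japonica. The values for 4-fold changes were 90.6%, 71.4%, 92.9%, 68.4% and 89.9%. The simulations gave between 91 and 177 calls per species, far fewer than the real comparisons, and the adjusted threshold depends on the number of calls. The recoveries and the share of false calls therefore hold for the simulated setting only. A gene without a call can still differ by 2-fold, at a rate that the simulation does not give. False calls made up 3.30% to 6.00% of the calls.

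C. elegans identifiers were matched to locus tags of RefSeq genes on assembly WBcel235, and 18532 of 19050 (97.3%) matched. That table was used for names, chromosomes and overlaps, and no coordinates are given because the build of the files is unknown. Overlapping genes and near-identical copies can share reads. Identifiers of the other species are not paired with symbols in the tables used here, so the planned comparison of like-named genes across species was left out.

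Comparisons, gene lists and alternatives were fixed before the data were examined, apart from those named as added. The lists were major sperm proteins, spermatogenesis, male mating structures, oogenesis and maternal genes, eggshell, vitellogenins, vulva and uterus, meiosis, germ granules and germline RNA control, DNA replication and cell cycle, sex determination, dosage compensation complex, muscle, intestine, neurons, collagens, moulting, early embryo, C-type lectins, cytosolic ribosomal proteins, histones and heat shock. A list of genes of the mitochondrial genome had 0 members in the table and was not tested. Genes named in the text came from a fixed panel, from the 10 strongest changes in each direction among symbol-bearing genes with non-overlapping sexes and a mean FPKM of at least 10 in the higher sex (at most 2 per symbol stem), and from the 2 to 4 most abundant called members of each list. Genes named as exceptions or minority members of a list, and sex-1, sdc-1 and lev-11, were chosen after their values were seen. The panel genes plg-1 and she-1 were not matched in the C. elegans table. X-linked and autosomal genes were compared by medians with 2000 bootstrap draws over genes.

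Alternatives were a pseudocount of 0.1, no filter and a filter at 5, median-of-ratios scaling, centring on the median change, a replicate block, a base-caller batch term, eBayes without trend and robust, a 2-fold threshold, the contig tables and leaving out each library in turn, with the tested genes kept as in the full fit. The planned DESeq2 alternative was for gene counts, which the gene tables do not give, and was not run. Added after seeing the data were fits without genes listed at 0 beside high values, without C. elegans XX replicates 2 and 3, and with replicates 2 and 3 alone. Also added were an unfiltered X comparison, the tests of changes over 16-fold, contig matching between species with blastn 2.17.0 (E-value 1e-05, reciprocal best hits) and tests of gene families. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

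Base-caller versions were compared as batches. With replicates 2 and 3 alone, XX-higher and XO-higher genes numbered 5145 and 6798 in C. elegans, 6842 and 8625 in C. remanei, 4920 and 7394 in C. brenneri, and 8110 and 4803 in C. japonica. Replicate 1 has a single library per sex and no test. In C. brenneri its XX and XO libraries also differed in base-caller version, so sex and version could not be separated there. The base-caller batch term set replicate 1 against replicates 2 and 3 and did not separate these versions. The median log2 change of replicate 1 was -0.44, -0.29, -0.29 and 0.40 in C. elegans, C. remanei, C. brenneri and C. japonica. In replicates 2 and 3 it was -0.33, -0.30, -0.48 and 0.39.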

Results

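Poly(A) RNA from whole animals of 5 Caenorhabditis species was sequenced separately for XX and XO animals. Each species and sex had 3 replicate libraries, 30 in all. C. elegans and C. briggsae are self-fertile, and their XX animals normally make sperm before oocytes. Mutants were used in both species so that the XX animals were female: fog-2(q71) in C. elegans and she-1(v47) in C. briggsae. C. remanei, C. brenneri and C. japonica have males and females, and wild-type strains were used. L4 larvae and young adults were picked by hand and pooled, at least 400 XX or 600 XO animals per replicate. C. briggsae was grown at 25 °C and the other 4 species at 20 °C. The contig tables gave between 5980705 and 24009713 mapped reads per library. The deposited gene tables held between 19050 and 23713 genes per species, as FPKM. Log2 changes are XX minus XO on the log2(FPKM + 1) scale, which understates the change of low genes.

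The first comparison asked how many genes differ between XX and XO animals within each species. Most expressed genes differed in all 5 species: 81.7% of 15611 genes in C. elegans, 67.3% of 15854 in C. briggsae, 86.1% of 18386 in C. remanei, 77.4% of 15929 in C. brenneri and 80.3% of 16130 in C. japonica. In C. elegans 5360 genes were higher in XX and 7390 in XO. The XX and XO numbers were 3386 and 7282 in C. briggsae, 6896 and 8932 in C. remanei, 5015 and 7319 in C. brenneri, and 8099 and 4859 in C. japonica. Changes over 16-fold lay mostly on the XO side in all 5 species, with 1619 XO-higher against 183 XX-higher genes in C. elegans, 1186 against 32 in C. briggsae, 1962 against 297 in C. remanei, 1466 against 191 in C. brenneri and 1293 against 246 in C. japonica. Called genes with a mean FPKM of at least 10 in XO and under 1 in XX numbered 1356, 1261, 2047, 1643 and 1033 in the same order. Among all genes, called or not, 60, 289, 175, 161 and 38 were listed at 0 in all 3 XX libraries beside at least 10 in all 3 XO libraries. A listed 0 can be a failed estimate. The reverse, a mean of at least 10 in XX and under 1 in XO, held for between 19 called genes in C. briggsae and 158 in C. remanei, with 137 in C. elegans.

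The balance between the sexes depended on scaling. The median log2 change of all genes tested was -0.39 in C. elegans, -0.48 in C. briggsae, -0.30 in C. remanei, -0.44 in C. brenneri and 0.39 in C. japonica. XO-higher genes made up 68.3% of the calls in C. briggsae as deposited, 48.1% when the median change was set to 0 and 55.0% under median-of-ratios scaling. In C. elegans the median lay at -0.20 under median-of-ratios scaling and at 0 with the centring, and changes of its genes below are given as deposited. The share of XO-higher calls went from 59.3% to 46.6% with the centring and to 55.8% under median-of-ratios scaling in C. brenneri, and from 37.5% to 49.5% and 51.3% under these scalings in C. japonica. The centring raised the XX-higher genes of C. briggsae from 3386 to 5526, and gave more XX-higher than XO-higher genes in C. elegans (6352 and 5937) and C. remanei (7833 and 7289). In C. briggsae the sexes also differed in strain, she-1(v47) against AF16, so sex and strain could not be separated there.

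**Figure D1:**
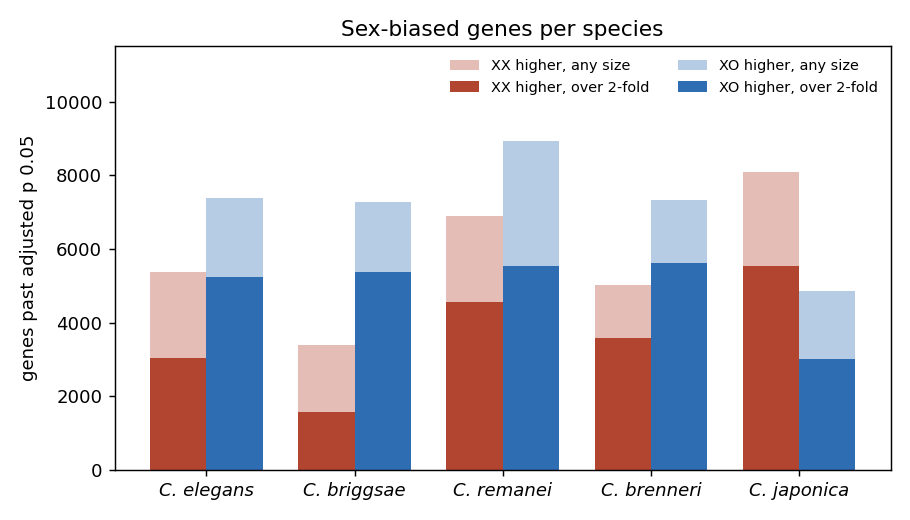
Number of genes per species (vertical axis) past an adjusted p of 0.05 in limma, higher in XX (red) or in XO (blue); pale bars hold all called genes and full bars those changed over 2-fold. XO bars are taller in 4 species and the XX bar is taller in C. japonica, with 8099 genes against 4859.

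Sperm genes had the lowest medians of the 22 lists in C. elegans. All 35 measured major sperm protein genes, which encode the cytoskeletal and signalling protein of nematode sperm, were higher in XO, with a median log2 change of -6.72 (camera adjusted p = 0.000423; adjusted p = 0.689 with an estimated correlation). Of 43 spermatogenesis genes 42 were higher in XO, with a median of -5.56 (camera adjusted p = 7.25e-09; adjusted p = 0.466 with an estimated correlation). The exception was spe-39, which also acts in vesicle trafficking outside sperm and was higher in XX by 0.82. The sperm phosphatase gene gsp-3 had 657 ± 19.9 FPKM in XO and 4.08 ± 4.58 in XX (SD, n = 3 each), and ssp-9 had 3301 ± 156 and 17.2 ± 18.9. The paternal-effect gene spe-11 had 198.6 ± 34.2 FPKM in XO and 0.685 ± 0.92 in XX (adjusted p = 1.02e-05), spe-9, needed for fertilization, changed by -3.79 and fog-3, which specifies sperm fate, by -4.88. The related fog-1 differed less, by -0.80 ± 0.10 (SE, adjusted p = 0.000253). Copies of the sperm protein genes are nearly identical, so that reads could be split among them, and msp-142 and msp-3 are uncertain as single genes.

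Male transcripts were not equally low in the 3 C. elegans XX libraries. Taken were list genes with at least 20 FPKM in XO and under 2% of that in XX replicate 1. The median FPKM of the sperm protein genes was 2.71, 44.7 and 111 in XX replicates 1, 2 and 3, against 3110 in XO. For 32 of 43 spermatogenesis genes it was 0.450, 2.22 and 1.06 against 158 in XO, and for 4 male mating genes 0.239, 1.90 and 0.212 against 117. With XX replicates 2 and 3 left out, a choice made after seeing the data, XX was a single library assumed to vary like the 3 XO libraries, which alone gave the spread. In that fit 35 of the 35 genes were called on the XO side, with a list median of -9.65, and all genes gave 4706 XX-higher and 7067 XO-higher calls.

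Genes of male mating structures were also higher in XO, all 14 measured, with a median of -2.73 (camera adjusted p = 0.000165; adjusted p = 0.433 with an estimated correlation). They included the polycystin genes lov-1 (-1.35) and pkd-2 (-3.47) of male sensory neurons, cwp-1 (-6.72), the male-specific regulator mab-3 (-5.11) and the seminal protease gene try-5 (-5.19). Mean FPKM of mab-3 was 73.0 ± 8.02 in XO and 1.18 ± 0.51 in XX (SD, n = 3 each). With the median change set to 0, 13 of the 14 were called.

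Oocyte, eggshell and yolk genes stood on the opposite side. Of 30 oogenesis and maternal genes 29 were higher in XX, with a median of 3.38 (camera adjusted p = 8.3e-12; adjusted p = 0.433 with an estimated correlation). The maternal regulators pos-1 and spn-4 changed by 5.48 ± 0.16 and 4.35 ± 0.13 (SE, adjusted p = 1.39e-06 for both), and puf-5 had 549 ± 70.1 FPKM in XX against 8.98 ± 2.93 in XO. The yolk receptor gene rme-2 changed by 4.32, gld-1 by 3.00 and oma-1, needed for oocyte maturation, by 2.35. The member without a call, mbk-2, was listed at 0 in XO replicate 3 and at 71.1 and 61.7 in the other XO libraries. All 17 eggshell genes were higher in XX, with a median of 3.95 (camera adjusted p = 5.26e-09; adjusted p = 0.433 with an estimated correlation). They included cbd-1 at 816 ± 109 FPKM against 25.0 ± 5.07, and the chondroitin proteoglycan genes cpg-1 (4.91) and cpg-2 (4.92).

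Of 6 vitellogenin genes, which encode yolk proteins, 5 were higher in XX by 7.09 to 7.20 (camera adjusted p = 0.00926; adjusted p = 0.484 with an estimated correlation). The gene vit-2 had 2958 ± 165 FPKM in XX and 20.8 ± 8.12 in XO, and vit-5 had 2866 ± 210 and 19.5 ± 8.12. The remaining gene, vit-6, was listed at 0 in all 3 XX libraries and at 20.7, 26 and 46.9 in XO. Abundant genes were also listed at 0 in single libraries, such as the tropomyosin gene lev-11, at 0 in XO replicate 1 and at 2800 and 2290 in the other XO libraries. The 0 of vit-6 is therefore given as listed, with no fold.

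**Figure D2:**
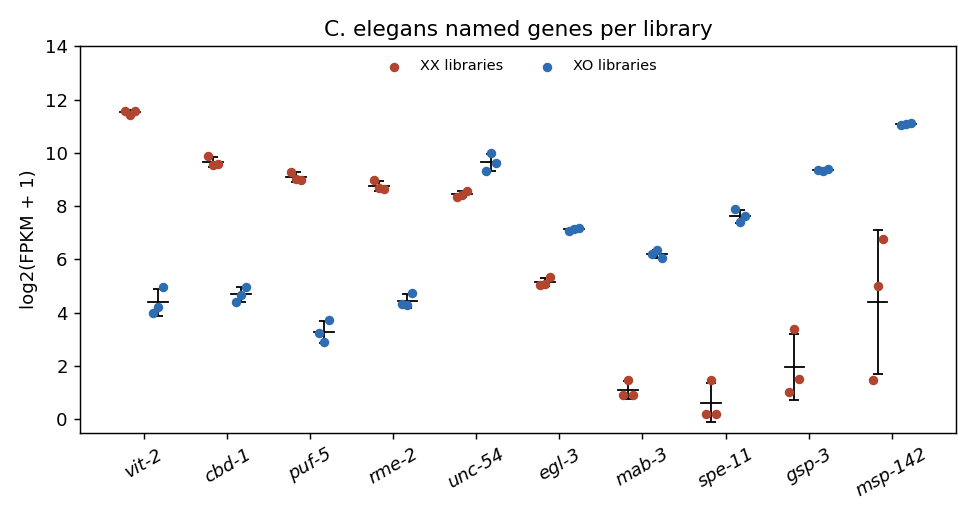
Expression of 10 C. elegans genes in each library, as log2(FPKM + 1) on the vertical axis; points are the 3 XX (red) and 3 XO (blue) libraries, with the mean and its SD of the log2 values in black. Yolk and oocyte genes lie higher in XX, sperm, male, muscle and neuronal genes higher in XO, and the 3 XX libraries spread most for msp-142.

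The lists of DNA replication and cell cycle, meiosis, germ granules and cytosolic ribosomal proteins were also on the XX side. Their medians were smaller than those of the oogenesis and eggshell lists. In DNA replication and the cell cycle 21 of 23 genes were higher in XX, with a median of 2.95 (camera adjusted p = 6.97e-09; adjusted p = 0.433 with an estimated correlation). The cyclin gene cyb-3 changed by 4.37, the replication clamp gene pcn-1 by 3.54 and rnr-2, of ribonucleotide reductase, by 3.87, while cyb-1 (-0.10) and bub-1 (0.20) were not called as deposited and were on the XX side with the centring. Of 23 meiosis genes 22 were higher in XX, with a median of 0.94 (camera adjusted p = 6.95e-07; adjusted p = 0.433 with an estimated correlation), among them him-5 at 1.35 and htp-1 at 0.72; syp-1, at 0.12, was not called. Of 19 germ granule and germline RNA genes 17 were higher in XX, with a median of 1.10 (camera adjusted p = 1.73e-05; adjusted p = 0.433 with an estimated correlation). The helicase gene cgh-1 changed by 2.78 and car-1 by 2.50, while glh-1 and glh-4 lay at -0.08 without a call. Cytosolic ribosomal protein genes were higher in XX in 54 of 63 cases with a median of 0.48 (camera adjusted p = 6.95e-07; adjusted p = 0.484 with an estimated correlation). With XX replicate 1 as the only XX library, and the spread from the XO libraries alone, 14 of the 63 were called on the XX side and the median was 0.43. The abundant rpl-39 and rpl-13 changed by 0.36 and 0.44. The rpl-39 call was lost without XX replicate 1 or 3 or XO replicate 1 or 3 (adjusted p from 0.0664 to 0.115), and the rpl-13 call without XX replicate 2 or 3 or XO replicate 1 or 3 (0.0678 to 0.113). The 1 gene on the XO side, rpl-42, had a mean of 0.124 FPKM in XX and 43.5 in XO.

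The sex determination list was split between the sexes. Of 13 genes 9 were higher in XX and 2 in XO, with a median of 0.82 (camera adjusted p = 0.0125; adjusted p = 0.433 with an estimated correlation). On the XO side were her-1, the secreted signal that promotes male fate, at -1.97 ± 0.18 (SE, adjusted p = 7.43e-05), and tra-1, the terminal regulator of somatic sex, at -1.10 ± 0.11 (adjusted p = 0.000116). On the XX side were fem-3 (2.32), fem-2 (1.65), sex-1 (2.49), sdc-1 (2.20) and tra-2 (1.46), the receptor for the HER-1 signal. The gene fog-2, mutant in both sexes here, had 4.64 ± 0.91 FPKM in XX and 3.55 ± 0.64 in XO (SD, n = 3 each; adjusted p = 0.145), and since both sexes carry the allele its level does not check the labels. It was called higher in XX under median-of-ratios scaling (adjusted p = 0.0282), with the centring (0.0092) and without XX replicate 1, where it changed by 0.44 (0.049). The remaining member without a call was fem-1, at 0.01. The gene xol-1, also of this list, was below the filter, at 0.820 ± 0.077 in XX and 0.715 ± 0.18 in XO. All 9 genes of the dosage compensation complex, which evens X-linked expression between the sexes, were higher in XX, with a median of 0.94 (camera adjusted p = 0.0027; adjusted p = 0.466 with an estimated correlation). Among them dpy-27 changed by 1.03 ± 0.15 (SE, adjusted p = 0.000657) and dpy-30 by 1.17. For sdc-2, at 1.37 FPKM in XX and 0.934 in XO, the call at 0.29 (adjusted p = 0.0385) was lost without XX replicate 1, 2 or 3 and without XO replicate 2 or 3, with adjusted p from 0.0617 to 0.102, with the smaller pseudocount (0.0508) and with a replicate block (0.0711). These 2 lists share 2 genes.

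Neuronal and muscle genes were mostly higher in XO, opposite to the oocyte and eggshell lists with medians of 3.38 and 3.95, and in RNA of whole animals a change in the share of germline tissue was not separated from a change within neurons or muscle. Of 17 neuronal genes 14 were higher in XO, with a median of -1.41 (camera adjusted p = 0.0027; adjusted p = 0.433 with an estimated correlation), such as the synaptic vesicle gene rab-3 (-3.84) and the neuropeptide-processing genes egl-3 (-1.99) and egl-21 (-2.09). The uncalled members were snb-1, unc-119 and unc-31, and with the centring 13 genes were XO-higher and 1 XX-higher. Of 20 muscle genes 17 were higher in XO, with a median of -1.12 (camera adjusted p = 0.00555; adjusted p = 0.52 with an estimated correlation). The myosin heavy chain gene unc-54 changed by -1.19 ± 0.18 (SE, adjusted p = 0.000721). Of the 3 without a call, lev-11 and unc-22 were each listed at 0 in a library and unc-60 was at 0.00. With the centring 15 muscle genes were XO-higher and 1 XX-higher, and act-2, at -0.45 as deposited, had no call under either other scaling (adjusted p = 0.138 and 0.613). C-type lectin genes, a family and not a tissue list, were higher in XO in 126 of 150 cases, with a median of -2.06 (camera adjusted p = 5.56e-09; adjusted p = 0.433 with an estimated correlation), but clec-87, at 1208 ± 231 FPKM in XX and 16.5 ± 3.80 in XO, was 1 of 13 on the XX side. The lectin gene clec-197 (-7.97), with 1156 FPKM in XO, was at 15.7 in XX replicate 2 and 1.78 in XX replicate 3, as for male transcripts. The intestinal list was not called by camera (adjusted p = 0.0757, median -1.07), with 13 of 19 genes higher in XO and 3 in XX. The saposin-like gene spp-5 and the protease gene asp-1 were at -1.50 and -1.26, and on the XX side stood cpr-5 (1.07), fat-7 (2.02) and the peptide transporter gene pept-1 (1.30). The protease gene cpr-6, at -0.33, changed sign to 0.05 with the centring. Under median-of-ratios scaling it was at -0.10 without a call (adjusted p = 0.397). Its call was also lost without XX replicate 1 or 3 or XO replicate 1 or 3 (adjusted p from 0.0613 to 0.0855).

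The other lists were not called as groups by camera. Collagens had 48 of 127 genes higher in XO and col-116, col-118, col-135, col-141 and col-153 higher in XX (adjusted p = 0.112, median -0.75), and the list passed the threshold without XX replicate 3 (adjusted p = 0.0327) or without XO replicate 1 (0.0499). The adult collagen gene col-19 was not called (-0.25 ± 0.22, SE, adjusted p = 0.32). Moulting genes, of which 8 of 17 were higher in XO and nas-37 and nhr-25 in XX, had a median of -0.43 (adjusted p = 0.489), and heat shock genes, 7 of 16 in XO and hsp-1, hsp-6, hsp-60 and hsp-12.6 in XX, had a median of -1.51 (adjusted p = 0.635). Under both other scalings 3 heat shock genes were XO-higher. Histones had 19 XX-higher and 18 XO-higher genes among 66 (median -0.08, adjusted p = 0.59), among them his-72 at 1.32 and his-70 at -7.02. The early embryo list of 6 genes had pes-10 and tbx-38 in XX and elt-1 and elt-3 in XO (median -0.29, adjusted p = 0.769). The vulva and uterus list of 8 genes had egl-26 and lin-3 in XX and lin-29, tph-1 and zmp-1 in XO (median -0.19, mean 0.14, adjusted p = 0.769). For histones and early embryo genes the direction in camera was XX, opposite to the sign of the median. The histone, early embryo and vulva medians changed sign to 0.31, 0.09 and 0.20 with the centring. Within the vulva list lin-3, the vulval inductive signal, was at 74.6, 70.6 and 73.1 FPKM in XX and at 0, 21.6 and 0 in XO, and its call was lost without any 1 library except XO replicate 2, with adjusted p from 0.0525 to 0.0888, and with a replicate block (0.0509). The early zygotic gene pes-10 had 3.88 ± 0.09 FPKM in XX and 0.063 ± 0.11 in XO. Adjusted over the list alone, the number of calls was the same except for intestine (14 in XO), collagens (42 in XO), moulting (6 in XO), histones (16 in XX) and ribosomal proteins (56 in XX).

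**Figure D3:**
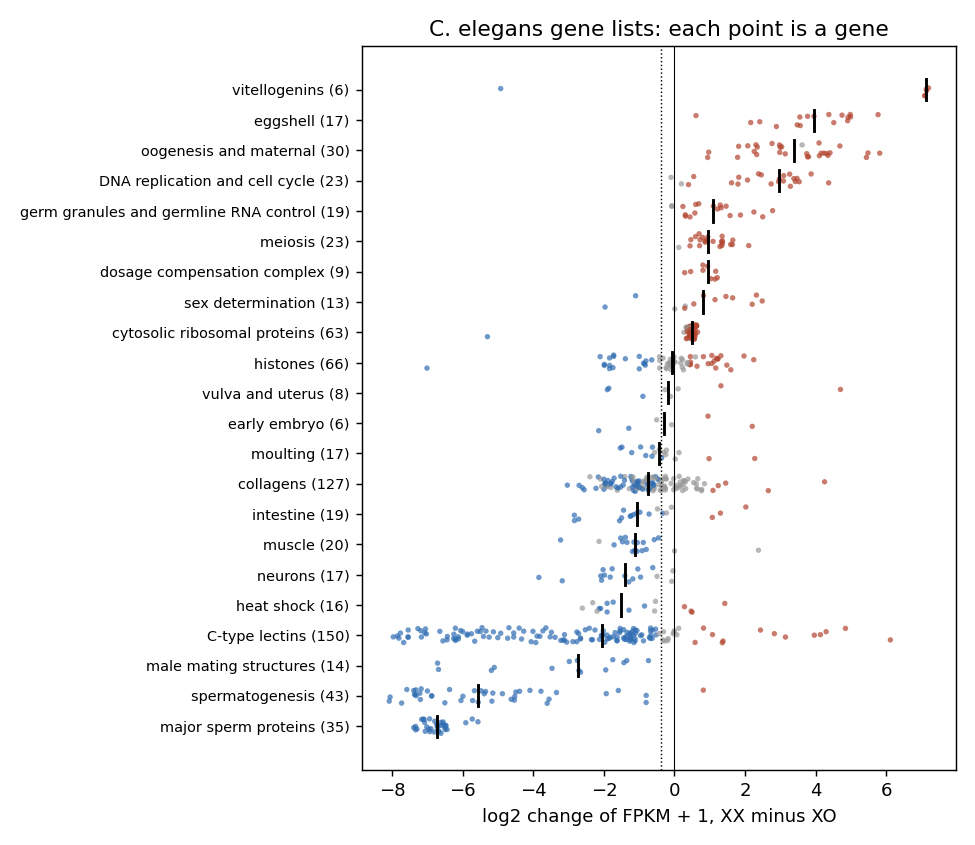
Log2 change of FPKM + 1, XX minus XO, of each C. elegans gene (points) in 22 lists, with the number of genes tested in brackets and the list median as a black bar; red points were called higher in XX, blue in XO and grey in neither. The dotted line marks the median of all genes, -0.39; medians run from -6.72 for major sperm proteins to 7.12 for vitellogenins.

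Among named C. elegans genes the strongest XX-higher changes were those of vit-5 (7.20) and vit-2 (7.15), the genes ule-4 (6.59) and ule-3 (6.58), stha-3 (6.33), mak-1, clec-87 (6.12), dod-23 (6.03), puf-5 (5.82) and cpg-3 (5.77). At most 2 genes per symbol stem were taken, and their XX and XO libraries did not overlap, as chance gives for 10% of genes. The gene mak-1 was listed at 0 in all 3 XO libraries and at 72.9 ± 2.38 FPKM in XX. On the XO side stood fipr-18 (-9.46), fipr-19 (-9.38), nspa-6 and nspa-7 (-9.04 each), srlf-18 (-8.52), nspd-10 (-8.45), msrp-2 (-8.44), fip-7 (-8.44), msrp-1 (-8.42) and nspd-2 (-8.32). The values of nspa-6 and nspa-7 were identical in all libraries, 27380 ± 3010 FPKM in XO, as for reads shared between copies. XX replicate 2 had the highest XX value for each of the 10 genes, and without it their changes lay between -11.03 and -9.31, all past the threshold.

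The C. elegans X chromosome was compared with the autosomes, since XO animals carry a single X. The X held 25 of its 1998 tested genes (1.25%) with XO-higher changes over 16-fold, against 1578 of 13213 autosomal genes (11.9%), an odds ratio of 0.0934 (Fisher's exact test, two-sided, p = 7.02e-69). XX-higher changes over 16-fold were found in 54 X-linked genes (2.70%) against 129 autosomal ones (0.976%), with an odds ratio of 2.82 (Fisher's exact test, two-sided, p = 6.3e-09). These tests over genes were added after seeing the data, and genes are not independent replicates. The median change was -0.49 on the X and -0.36 on the autosomes, a difference of -0.12 with a bootstrap 95% interval over genes from -0.21 to -0.04, which became -0.29 with a filter at 5 and -0.08 with no filter. In the mean the order was opposite, -0.22 on the X and -0.77 on the autosomes, and camera did not call a shift of the X-linked genes (p = 0.375, and p = 0.639 with an estimated correlation). Medians of single autosomes ran from -0.74 on chromosome V to 0.08 on chromosome I, so the X lay within their range.

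**Figure D4:**
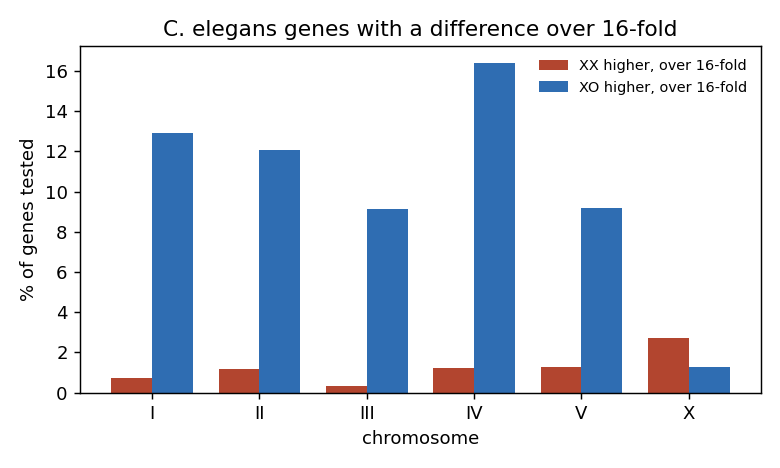
Percent of the C. elegans genes tested on each chromosome (horizontal axis) that were called with a change over 16-fold, higher in XX (red) or in XO (blue). The XO share is 1.25% on the X and between 9.15% and 16.4% on the autosomes.

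In the other 4 species the tables give gene identifiers without names, and 2 genes per direction are given for each. In C. briggsae, CBG14608 had 4013 ± 1290 FPKM in XX against 5.42 ± 4.28 in XO, and CBG14203 had 3155 ± 965 against 14.6 ± 8.39. On the XO side, CBG20892 reached 26200 ± 5810 against 0.559 ± 0.52, and CBG17970 reached 25400 ± 6070 against 0.494 ± 0.43. In C. remanei the XX-higher genes were CRE00395 (7.40 ± 0.21, SE, adjusted p = 4.02e-08) and CRE00388 (7.39 ± 0.23, adjusted p = 5.32e-08). The XO-higher genes were CRE01691 (-12.30) and CRE15242 (-11.88), and the former reached 156300 ± 43600 FPKM. In C. brenneri CBN25808 (8.31) and CBN21878 (8.09) were higher in XX, and CBN19867 (-11.85) and CBN23760 (-11.53) in XO. In C. japonica CJA28095 (10.11) and CJA04254 (9.15) were higher in XX, and CJA24508 (-11.77) and CJA21541 (-11.25) in XO.

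The share of expressed genes was set side by side across species without a test, because the tables were normalized separately and 2 self-fertile against 3 male-female species cannot give an exact permutation p below 0.1. Genes with an FPKM of at least 1 in at least 3 libraries made up 81.9% of the table in C. elegans and 81.2% in C. briggsae. The values in the male-female species were 77.5% in C. remanei, 75.8% in C. brenneri and 82.6% in C. japonica.

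The assembled contigs gave a second view of the same libraries. Higher in XX and in XO were 8154 and 8381 contigs in C. elegans, 7169 and 5751 in C. briggsae, 19352 and 16531 in C. remanei, 23719 and 22703 in C. brenneri, and 29803 and 18638 in C. japonica. The median log2 change was above 0 in all 5 species, at 0.05, 0.09, 0.23, 0.13 and 0.45 in that order, while the gene tables of 4 species had medians below 0.

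The authors' deposited table marked 3444 XX-higher and 5090 XO-higher genes as differential in C. elegans, 2609 and 7115 in C. briggsae, 5367 and 6252 in C. remanei, 2369 and 3700 in C. brenneri, and 6346 and 3404 in C. japonica. Among the genes tested here, between 99.6% and 99.8% of those marked as differential in the authors' deposited table were also called by limma. Of all genes tested, limma called between 67.3% and 86.1%, and the direction of the marked genes was not compared. In C. elegans 8066 of the 12750 limma calls carried the authors' mark.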

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

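All tests of explanations in this part were chosen after the results were seen, as was the criterion for contigs high in a single library (at least 20 RPKM and over 10 times every other library, or every other XX library), except for the splits of the libraries.

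In C. japonica the median log2 change was 0.39 and each XX library had a higher median than each XO library, whereas in the other 4 species each XX library lay below each XO library, a difference between species that was not tested. Dominance of a few genes was not decided. With the share of the 10 highest genes in summed FPKM taken out of each library, the C. japonica median was 0.32. It lay 0.765 above the next, -0.44 in C. elegans, while the C. remanei median went from -0.30 to -0.79. The share of reads held by these genes was not computed, and a share of FPKM does not replace it, so no conclusion is drawn. The scaling of the gene tables cannot be told apart from a real difference, because all 5 medians were above 0 in the contig tables, where C. japonica still lay 0.216 above the next species (bootstrap 95% interval 0.192 to 0.241), and median-of-ratios scaling turned C. japonica to 6565 XO-higher against 6228 XX-higher genes. Which genes are counted also stays open: over short contigs matched by sequence the C. japonica median was itself below 0 against each species, from -0.22 to -0.08, and exceeded that of C. elegans by 0.0513 (-0.00975 to 0.0977), C. remanei by 0.147, C. brenneri by 0.161 and C. briggsae by 0.192. A biological difference between the species stays open and untested.

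C. elegans XX replicate 2 held more of 3 groups of male transcripts than XX replicate 1 and XX replicate 3 more sperm protein transcripts, in genes chosen as low in XX replicate 1, and the contig table, outside the main comparison, showed 21 contigs high in XX replicate 3 alone. In XX replicate 2 the excess over XX replicate 1 was 1.31% of the XO level for sperm proteins, 1.03% for spermatogenesis and 1.16% for 4 male mating genes. The first 2 differed 1.27-fold (bootstrap 95% interval over genes 1.12 to 1.37), and also 1.27-fold with no condition on XX replicate 1. RNA of C. elegans males at about that share could give such values. The bootstrap intervals here take genes as independent, though copies of sperm protein genes can share reads, and each excess compares single libraries. They therefore understate the uncertainty. In XX replicate 3 the excess was 3.89% for sperm proteins and 0.166% for spermatogenesis, 23.4-fold apart (13 to 149). With no condition on XX replicate 1 the 2 lists lay 23.5-fold apart (13 to 3818). For male mating genes the excess was -0.0630% (0.00541% with no such condition). These values argue against RNA of whole C. elegans males as the source of the whole excess. RNA of a part of the male, such as sperm alone, was not tested. Of 86 contigs raised in XX replicate 3 over the other XX libraries, chosen without XO, 65 had a lower mean in XO (75.6%, exact binomial interval 65.1% to 84.2%). The numbers were 0 of 14 raised in XX replicate 2 and 23 of 23 in XX replicate 1. This argues against C. elegans males as the source of most of the contigs raised in XX replicate 3. Of the 21 contigs 17 matched a C. remanei contig, against 25.0% of all C. elegans contigs. Of those matches 76.5% were XO-higher in C. remanei against 44.4% of all (exact binomial test, one-sided, p = 0.00743, adjusted p = 0.0297 over the 4 species tried, contigs taken as independent). In the other species 4 of 4 were XO-higher in C. brenneri (adjusted p = 0.0459), 4 of 5 in C. briggsae (0.0726) and 0 of 1 in C. japonica. RNA from males of another Caenorhabditis species may therefore be present, but was not shown. The median identity of the 17 matches was 90.4%, against 87.5% for all C. elegans contigs with a C. remanei match. Matches at such identity do not tell RNA of another species from C. elegans RNA. Carry-over from the C. remanei libraries was argued against, as 0 of the 17 matches reached 97% identity, and no biological explanation was tested.

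In C. elegans 171 genes were listed at 0 in 1 library and at 10 FPKM or more in both others of that sex. Low depth was argued against, because XX replicate 1 held 85 of these zeros and the shallowest library, XX replicate 3, held 20. Of the 171, 110 matched a locus tag and passed the expression filter. Overlap with another gene was argued against as the main cause in these, since 31.8% overlapped one (exact interval 23.3% to 41.4%). The share was 26.4% of the other matched genes tested (Fisher's exact test, p = 0.195). Reads shared between near-identical copies cannot be told apart from other failures of estimation. A row of identical values elsewhere in the table was found for 26.3% of all 171 genes, including those below the filter. It was found for 1.02% of the other genes tested, all past the filter, and copies with unequal values could not be recognised. No biological explanation was tested.

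Among the other libraries, those with at least 10 contigs high in that library alone were C. brenneri XO replicates 1, 2 and 3, with 65, 14 and 18, and C. remanei XO replicate 1, with 11. C. briggsae and C. japonica libraries had at most 7.

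With 3 libraries per sex there are 10 splits of the 6 libraries, too few for a share under 0.05. In each species 1 of the 10 splits, the real one, called as many genes in limma, with 12750 in C. elegans, 10668 in C. briggsae, 15828 in C. remanei, 12334 in C. brenneri and 12958 in C. japonica, and the highest number in any other split was 0. Each other split mixes the sexes in both groups, so the sex difference adds to its spread. A low number there was to be foreseen, and no conclusion is drawn from it.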

How the results depend on the processing

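The fits without genes listed at 0, without C. elegans XX replicates 2 and 3 and with replicates 2 and 3 alone, and the male transcript test with no condition on XX replicate 1, were chosen after seeing the data. DESeq2 was planned for gene counts and was not run, because the gene tables hold FPKM. The planned restriction of the X comparison to genes changed at most 2-fold selects on the change compared and decides nothing. All counts of sex-biased genes kept within 1.5 times their value under the other pseudocount, no filter, median-of-ratios scaling, eBayes without trend and robust and the batch term, which was not run in C. briggsae. Where they did not under other settings, the cause was not tested unless given. A 2-fold threshold left 3037 XX-higher genes in C. elegans, 1563 in C. briggsae, 4571 in C. remanei with 5538 XO-higher ones, and 3003 XO-higher genes in C. japonica. A filter at 5, which tests fewer genes, left 4809 XO-higher genes in C. briggsae and 4660 in C. brenneri. Centring gave 5526 XX-higher genes in C. briggsae. Contig tables, which hold more features, gave 8154 XX-higher contigs in C. elegans, 7169 in C. briggsae, 19352 in C. remanei, 23719 in C. brenneri and 29803 in C. japonica, and 16531, 22703 and 18638 XO-higher contigs in the last 3. Without each library in turn, XX-higher genes ranged from 5104 to 5261 in C. elegans, 2665 to 3928 in C. briggsae, 6659 to 6856 in C. remanei, 4483 to 5104 in C. brenneri and 7755 to 8096 in C. japonica. XO-higher genes ranged from 7082 to 7275, 6309 to 7685, 8440 to 8868, 6541 to 7536 and 4608 to 4782 in that order, and the X difference from -0.17 to -0.09. Without genes listed at 0, C. briggsae, with the most such genes, had 3376 and 6979 calls. The histone list (median -0.0775) turned from XX in camera to XO in fry (adjusted p = 0.00987), and cpr-6 turned to 0.0512 with centring. Among the alternatives of 125 named genes, 2039 values kept direction and side of the threshold, 73 lost the call, 4 gained one and 1 reversed. Of 22 lists, 15 lost the call with the estimated correlation, and intestine (adjusted p = 0.000153) and vulva and uterus (0.00332) gained one in fry, which does not compare a list with other genes.

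Replicate numbers did not pair the samples throughout. Same-number correlations of deviations were 0.329, 0.0472 and 0.099 in C. elegans and fell below 0.1 for at least 1 number in each other species. For replicate 1 the correlation was positive in every species, at 0.199 in C. briggsae, 0.181 in C. remanei, 0.18 in C. brenneri and 0.202 in C. japonica. A batch shared by the XX and XO libraries of replicate 1 is therefore left open. The number of libraries correlating best with their own number was 3, 4, 5, 3 and 2 of 6 in C. elegans, C. briggsae, C. remanei, C. brenneri and C. japonica. With a replicate block, XX-higher and XO-higher genes numbered 5349 and 7340, 3186 and 7227, 6988 and 9113, 5002 and 7374, and 8164 and 4889 in these species.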

Other observations

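The contig matching and the family tests in this part were chosen after seeing the data.

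Sex bias was shared between species where sequence allowed a comparison. Short contigs paired by reciprocal best match between 2 species, 1867 to 5130 per pair, had log2 changes that correlated across contigs with Pearson's r from 0.751 to 0.872 and Spearman's rho from 0.674 to 0.824 in 10 pairs of species, while shuffled matches gave at most 0.0618. Contigs are not independent replicates, and no p is given. The highest rho was that of C. remanei and C. brenneri, where 2361 of 2429 contigs called in both had the same direction (97.2%, against 51.5% for independent directions). The lowest rho was that of C. briggsae and C. japonica, where 639 of 704 had the same direction (90.8%, against 50.2%). Of 435 C. elegans contigs matched in all 5 species, 104 were called in all 5, of which 28 were higher in XX and 63 higher in XO throughout. That is 87.5% with 1 direction, against 15.7% for independent directions. The 13 others had mixed directions, and in 5 of them C. japonica alone was higher in XX, as were C. remanei in 2 and C. briggsae in 1, while C. elegans and C. brenneri were each alone in XO in 1.

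Neuropeptide and receptor families stood out on the XO side in C. elegans. All 31 FMRFamide-like peptide genes (flp) were higher in XO, with a median log2 change of -2.16, as were 65 of 74 neuropeptide-like genes (nlp, -1.66), 25 of 26 neuropeptide receptor genes (npr, -0.98) and 26 of 28 ligand-gated channel genes (lgc, -1.21). Their adjusted p in a one-sided Fisher's exact test over 262 family tests was 8.4e-11, 1.35e-14, 1.27e-07 and 3.54e-07, against 41.7% XO-higher among 8161 symbol-bearing genes tested. The test takes genes as independent, which members of a family are not. The neuron list had an adjusted p of 0.433 in camera with an estimated correlation. The family counts are as deposited, and a change in the share of germline tissue was not separated from a change within these families. Glucuronosyltransferase genes (ugt) were XO-higher in 44 of 53 cases. On the XX side stood mitochondrial ribosomal proteins (mrpl, 36 of 40, median 0.74, adjusted p = 5.37e-09), nuclear pore proteins (npp, 24 of 25, 1.40, adjusted p = 1.77e-07) and Mediator subunits (mdt, 19 of 20, 1.35, adjusted p = 8.68e-06). Families were taken as genes sharing a symbol stem, with at least 10 tested. Of 131 such stems 25 passed the threshold on the XX side and 40 on the XO side. Some of these stems, such as unc, egl and him, are naming classes and not families of related genes.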
